A study of Mus musculus with 6 samples.

How the data were processed

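Intestinal RNA of mice was measured in 6 libraries, 3 labelled HET and 3 labelled WT, and groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was taken up with oligo(dT) beads and libraries were made with a SMARTer mRNA-seq kit. The authors deposited 1 table of FPKM values, that is reads scaled by gene length and library total, with gene symbols and 1 column per library. The genome build was GRCm39 per the submitters' processing notes. The aligner, the counting tool, the gene annotation and the use of strand are not given in the sources used here. The labels also name a table of raw counts, which was not used here. No coordinates are printed because the reference in use was GRCm38.p6, which served for gene names, transcript lengths and the chromosome of each gene.

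The table held 21959 rows. The 51 rows without a symbol held at most 0.021% of the FPKM of a library and were left out of tests. For 23 rows with a repeated symbol, the row with the highest mean was kept. FPKM values of a gene were whole multiples of what 1 read is worth, so whole reads and library totals could be recovered. All 12488 of 12488 genes tried gave whole reads in all 6 libraries, within a tolerance of 0.001 of a read, and library totals were 14872105 to 19549709 reads. Pairs of libraries within a group differed by a chi-square per gene of 35.3 to 424.6, above counting noise alone. This does not show whether libraries come from separate animals or are repeat preparations.

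Genes with a mean of at least 0.5 FPKM over the 6 libraries were tested, 12519 in all. Values were taken as log2(FPKM + 1), with a pseudocount of 1, and fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), 2-sided, HET against WT with no covariate. Adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale and are given with limma's moderated standard error (SE) or 95% confidence interval. Replicate spread is given as SD of FPKM over 3 libraries. FPKM share 1 total per library, so a group of very abundant transcripts in a library lowers all others there. FPKM are not counts, and the test does not use the number of reads behind each value. Genes that share sequence with a close copy depend on how the authors' counting treated such reads.

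Gene lists, 60 in number with 1507 different genes, of which 1461 had a row and 1293 were tested, were written before the data were examined. They cover pathways, intestinal cell types, intestinal regions and other tissues. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 60 lists, and again with camera at an estimated correlation and with fry. Camera compares a list with all other tested genes, and fry tests whether its genes move on balance in one direction. The estimated-correlation p of each described list is given beside it, since no list passed in that setting.

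The named genes were fixed by a rule before the data were examined. Per direction, the rule takes the 12 genes with the largest absolute log2 fold change among those past the threshold whose 3 HET values all lie on one side of the 3 WT values. It adds Pten and Nedd8, and up to 4 members of each described list, those past the threshold first and then those with the smallest unadjusted p. Predicted genes with systematic names, 2 of the called genes, were counted and not named. The genes of pancreatic, regional or other checks that fall outside this rule, such as Pnlip, Ins2, Nox1, Bdh1, Reg3a, Reg3b and those named in the closing section, were chosen after their values were seen.

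Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter and a filter of 5 FPKM, rescaling to TPM, median-of-ratios scaling, quantile normalization, leaving out mitochondrial and the 20 most abundant genes, eBayes without a trend and with robust estimation, array weights, leaving out each library, a replicate block, an adjusted p under 0.10, and an unadjusted p under 0.05 with at least a 2-fold change. Chosen after seeing the data were limma's voom on the recovered reads, rescaling without 61 pancreatic transcripts, and a score of the ileum list or of the duodenum and jejunum list as a covariate. The pancreatic transcripts were the list and genes at least 20-fold higher in WT 3 than in every other library and at least 10 FPKM there.

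The per-gene test was tested on simulated values with the real genes' means and spread. Each gene was drawn independently with the same spread in all 6 libraries. A library that shifts most genes together, as WT 3 does, was not simulated. For HET against WT over 12519 genes, 65 of 100 genes changed by a log2 fold change of 1 and 95 of 100 changed by 2 were called with the right sign, and 15 unchanged genes were called as well. A simulated list shifted by 1 was called, and 0 of 59 unshifted lists were. These lists held random genes simulated independently of each other. They do not show how often the preset correlation calls lists of co-regulated genes. The read recovery returned all 200 simulated genes. Reads were recovered with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.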

Results

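Polyadenylated RNA from mouse intestine was sequenced in 6 libraries, 3 labelled HET and 3 labelled WT for a PTEN-NEDD8 fusion gene. PTEN is a lipid phosphatase that opposes PI3K signalling, and NEDD8 is a ubiquitin-like protein that is attached to cullins. The comparison asked how intestinal transcripts differ between the 2 genotypes. The part of the intestine, the age and the feeding of the animals are not given in the labels. The HET libraries held 17351685, 19404449 and 17262535 reads, and the WT libraries held 19549709, 16554349 and 14872105 reads, as recovered from the deposited FPKM values. The labels do not say whether the 3 samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

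One library stood apart. In WT 3, the fixed list of pancreatic acinar and digestive enzyme genes took 43.5% of the summed FPKM, against 0.505% to 0.653% in each of the other 5 libraries. The protease gene Ctrb1 reached 32797 FPKM in WT 3, the lipase gene Pnlip reached 11696 FPKM and the insulin gene Ins2 reached 27.5 FPKM. Pnlip and Ins2 were listed at 0 in the other 5 libraries, and Ctrb1 was at 0 to 0.344 FPKM there. The list gene Zg16 was at 1225 to 2001 FPKM in those 5 libraries, so their list share is not one of pancreatic enzymes alone. All transcripts of a library share 1 read total, so a share of this size lowers the FPKM of the remaining genes in WT 3. The median log2 fold change of all tested genes, HET against WT, was 0.13 with WT 3 and 0.07 without it, was 0.26 after rescaling to TPM, and was 0.0055 after the pancreatic transcripts were left out. Medians of gene lists are therefore given relative to the median of all tested genes.

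**Figure D1:**
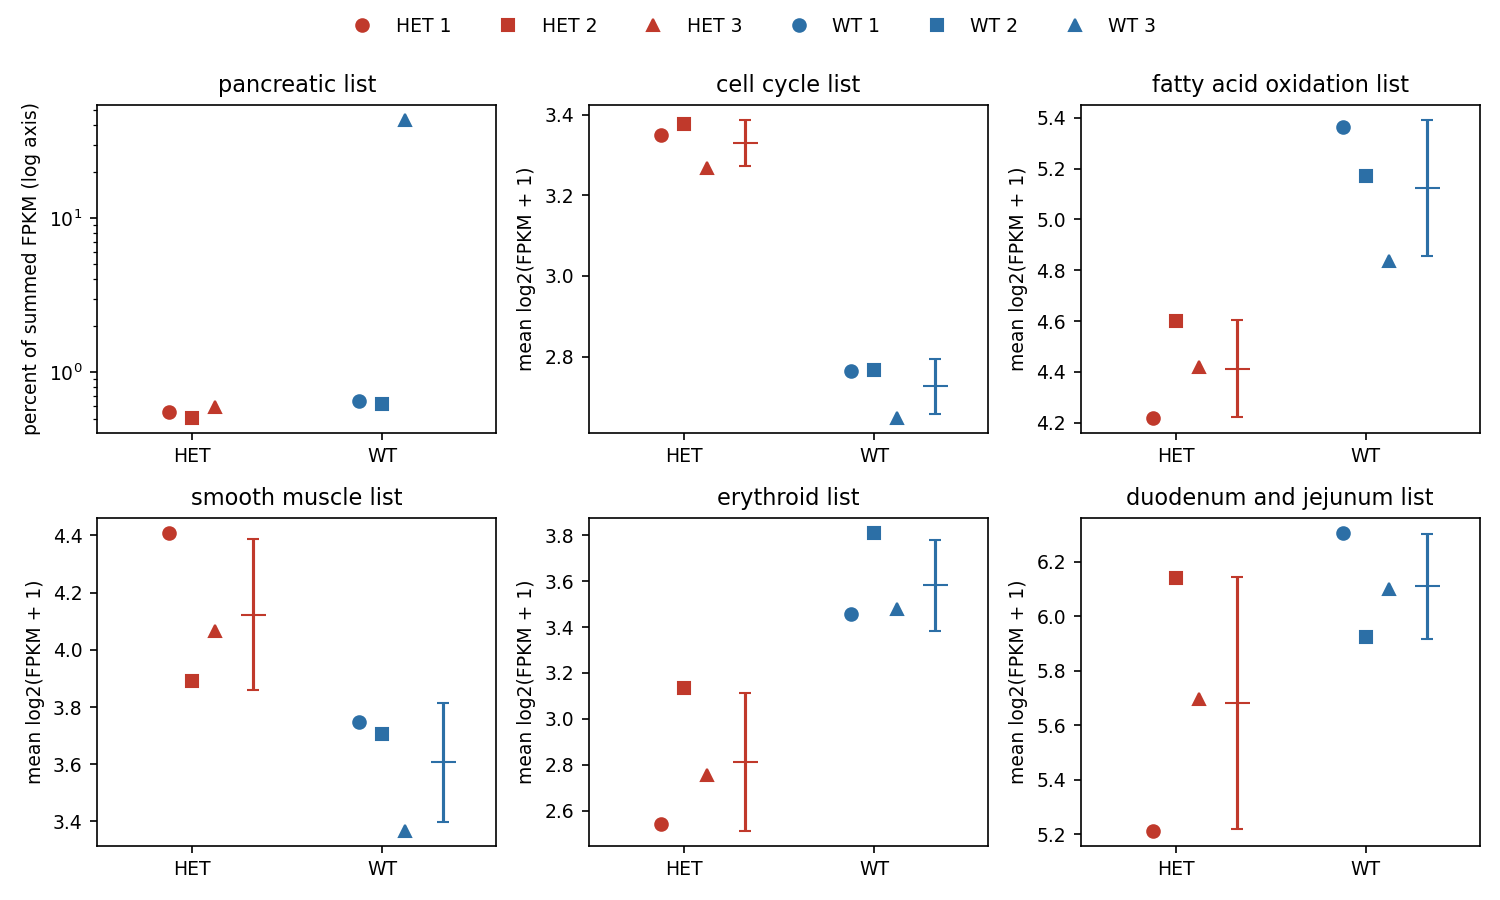
Per-library share of the pancreatic list in the summed FPKM (log axis, percent) and mean log2(FPKM + 1) of 5 other gene lists without the pancreatic transcripts, for 3 HET (red) and 3 WT (blue) libraries. Points are single libraries, and bars in the panels other than the pancreatic one are the mean ± SD of 3 libraries. WT 3 holds 43.5% pancreatic transcripts, and the 3 HET libraries lie above the 3 WT libraries for the cell cycle and smooth muscle lists and below them for the fatty acid oxidation and erythroid lists. List means are not relative to all tested genes.

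Transcripts of the 2 fusion partners did not differ detectably between the groups. Pten was measured at 16.1 ± 0.549 FPKM in HET and 16.0 ± 2.14 FPKM in WT (SD, n = 3 each), a log2 fold change of 0.02 with a 95% confidence interval of −0.32 to 0.35. Nedd8 was measured at 34.6 ± 2.40 FPKM in HET and 33.6 ± 5.80 FPKM in WT, a log2 fold change of 0.06 with a 95% confidence interval of −0.34 to 0.45. The values were 15.6, 16.7 and 16.0 in HET and 17.9, 16.4 and 13.7 in WT for Pten, and 34.1, 32.5 and 37.3 in HET and 32.4, 39.9 and 28.4 in WT for Nedd8. The limma adjusted p was 0.959 for Pten and 0.892 for Nedd8. Both signs turned negative without WT 3, at −0.08 and −0.05, and that of Pten also without HET 2, at −0.0071. It is not known whether reads of the fusion transcript fall in either row, so these values do not check the genotype labels.

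Among genes past the adjusted p threshold, Gsdmc4 and Duox2 had the largest rises in HET intestine and Hmgcs2 and Cyp4a10 the largest falls. The pancreatic gene Ctrb1 had a larger fall than Hmgcs2, a log2 fold change of −5.07, that did not pass (adjusted p = 0.492). Gsdmc4, a member of the pore-forming gasdermin C family, rose 69.1-fold, and Duox2, an oxidase that makes hydrogen peroxide at the epithelial surface, rose 33.1-fold. Hmgcs2, the rate-limiting enzyme of ketone body synthesis, was 17.1-fold lower, and Cyp4a10, a fatty acid hydroxylase and target of PPAR alpha, was 14.9-fold lower. The heat shock gene Hspa1b was 7.90-fold lower and Cyp1a1, a monooxygenase induced through the aryl hydrocarbon receptor, was 6.79-fold lower. Folds are on the FPKM + 1 scale, which understates the change of low genes. Of 12519 genes tested, 99 were higher and 20 lower in HET at a limma adjusted p under 0.05, with 39 of them at least 2-fold higher and 18 at least 2-fold lower. In each of the 119 genes, the 3 HET libraries lay on one side of the 3 WT libraries, and 24.2% of all tested genes were separated in this way, against 10% by chance. Of these, 347 were lower and 2687 higher in HET, and higher is the direction in which the pancreatic share of WT 3 moves the other genes.

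The split into higher and lower genes depended on the scaling. Median-of-ratios scaling called 14 genes higher and 17 lower, quantile normalization called 25 higher and 22 lower, and leaving out the pancreatic transcripts with rescaling called 13 higher and 23 lower, with the sign of all 119 genes kept in these 3 scalings. Without WT 3, 119 genes were higher and 92 lower, and 104 of the 119 genes remained past the threshold. The number of called genes fell when any other library was left out, to 14 without HET 1, 29 without HET 2, 8 without HET 3, 6 without WT 1 and 24 without WT 2. Among the genes named here, Hmgcs2, Cyp4a10, Hspa1b and Hspa1a stayed past the threshold with each library left out. Duox2 and Duoxa2 did so for 4 of 6 libraries, Gsdmc4 for 2, most others for 1 or 2, and Ubd and Pik3cg for 0. Other genes were as stable as Duox2 and Duoxa2, which passed in 18 and 17 of 22 alternative settings, left-out libraries included. Hsd17b13, Cyp2c55 and AA467197 passed in 19, 18 and 18 of these.

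**Figure D2:**
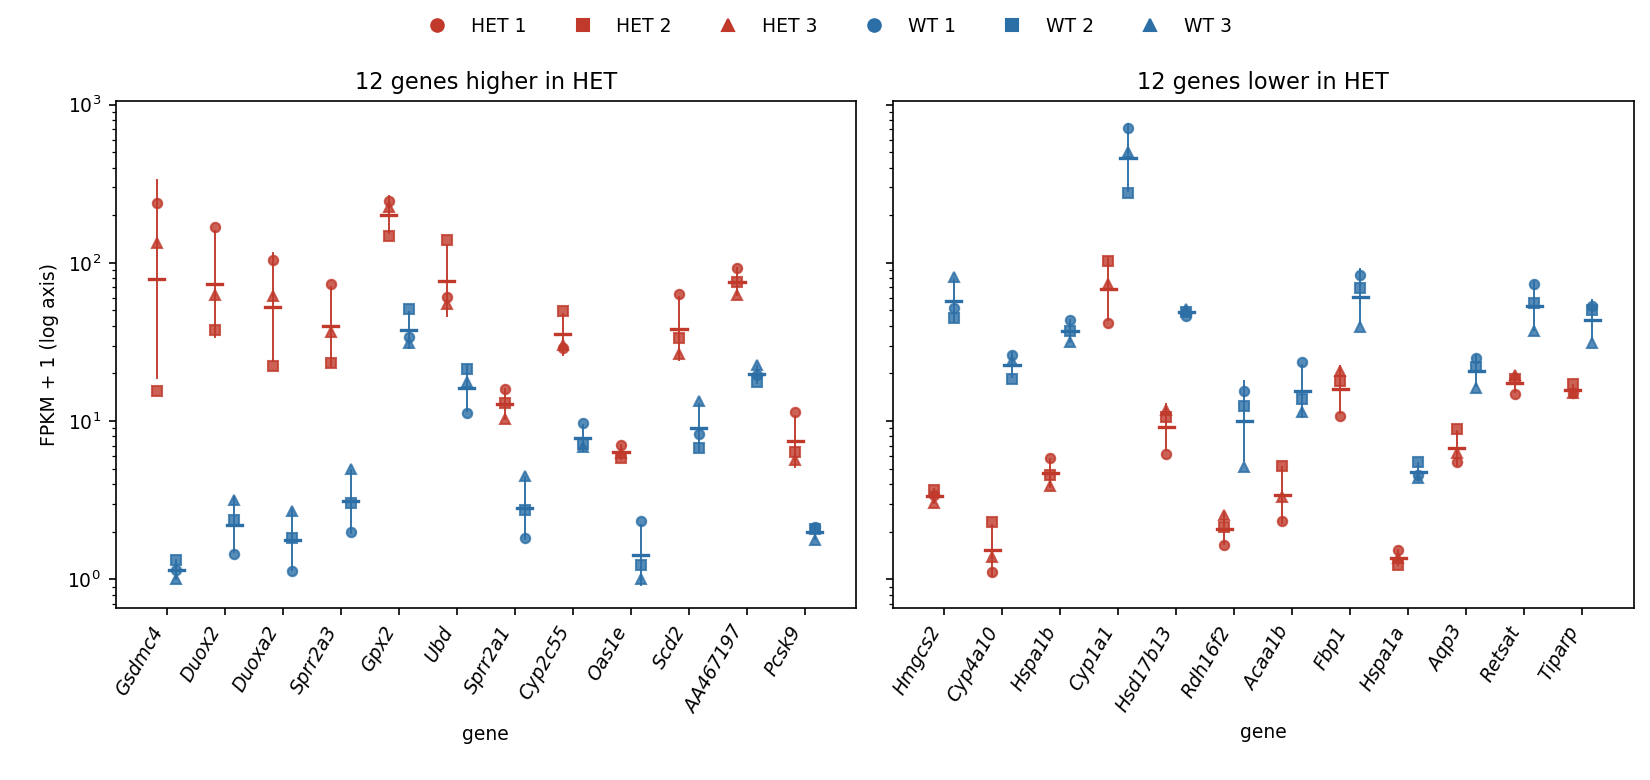
FPKM + 1 (log axis) of the 12 genes with the largest rise and the 12 genes with the largest fall in HET among genes past the adjusted p threshold. Points are single libraries (HET red, WT blue), horizontal lines are means on the log scale and vertical lines are ± SD over 3 libraries. In each gene the 3 HET libraries are apart from the 3 WT libraries; Gsdmc4 spans 14.6 to 238.7 FPKM among the HET libraries.

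Of the lists of epithelial antimicrobial and type 2 response genes, 6 different genes rose and most members did not pass. Duox2 rose from 1.33 ± 0.861 to 88.8 ± 70.0 FPKM (SD, n = 3 each, log2 fold change 5.05 ± 0.52 SE, adjusted p = 0.0154). Its maturation factor Duoxa2 rose from 0.884 ± 0.782 to 61.8 ± 40.9 FPKM (4.88 ± 0.54 SE, adjusted p = 0.0185). Gsdmc4 was covered by 6, 11 and 0 reads in the WT libraries and by 8644, 591 and 4778 reads in the HET libraries (6.11 ± 0.86 SE, adjusted p = 0.0322). The small proline-rich genes Sprr2a3 and Sprr2a1 rose by log2 fold changes of 3.68 and 2.18, and the superoxide-producing oxidase Nox1 rose by 0.93. The Sprr2a copies and the Gsdmc copies are near-identical in sequence, so the split of reads between copies is uncertain. In the list of inducible antimicrobial and barrier genes, 5 of 22 tested members rose, none fell and 17 did not pass, with 9 higher and 2 lower when adjusted over the list alone. The 2 lower ones were the antimicrobial lectin genes Reg3a and Reg3b, at log2 fold changes of −1.51 and −1.59. The list median was 0.88 above that of all tested genes. Without WT 3 it was 0.86 above, and 5 members rose and 1 fell past the threshold over all genes. In the list of type 2 epithelial response genes, named for the response to parasites, 3 of 16 rose and none fell, with 13 higher when adjusted over the list alone, at a relative median of 1.43. In that list the goblet cell gene Clca1 had a log2 fold change of 1.54 and an adjusted p of 0.0532. Camera with a preset correlation gave adjusted p = 0.00313 for the antimicrobial and 8.95e-09 for the type 2 list. With an estimated correlation the adjusted p was 0.424 and 0.412, and both lists passed by fry at an adjusted p of 0.0152. The smooth muscle list mean was also higher in each HET library, at 3.89 to 4.41 on the log2 scale against 3.37 to 3.75 in WT. These means are not relative to all tested genes. The lowest was that of WT 3, whose FPKM its pancreatic share lowers, and WT 1 and WT 2 were at 3.75 and 3.71.

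Of 33 genes of fatty acid oxidation, ketone body synthesis and PPAR targets, Hmgcs2, Cyp4a10, Acaa1b and Acot1 fell in HET intestine. Hmgcs2 went from 58.5 ± 19.5 FPKM in WT to 2.37 ± 0.328 FPKM in HET (SD, n = 3 each, log2 fold change −4.10 ± 0.23 SE, adjusted p = 0.00131). Cyp4a10 went from 21.8 ± 3.95 to 0.596 ± 0.621 FPKM (−3.89 ± 0.27 SE, adjusted p = 0.00181). Acaa1b, a peroxisomal thiolase, and Acot1, an acyl-CoA thioesterase, fell by 2.18 and 1.35 on the log2 scale. Reads of Cyp4a10, Acaa1b and Acot1 can be shared with close paralogs. Of 33 tested members of the list of fatty acid oxidation, ketogenesis and PPAR targets, 4 fell, none rose and 29 did not pass. Adjusted over the list alone, 1 rose (Bdh1, a ketone body enzyme, at a log2 fold change of 0.60) and 13 fell. The relative list median was −0.53 with all libraries and −0.62 without WT 3, where 9 members fell. Camera gave adjusted p = 3.20e-17, with an estimated correlation the adjusted p was 0.424, and by fry it was 0.0934. The list of genes high in the duodenum and jejunum moved the same way, with a relative median of −0.79, no single member of 20 past the threshold, over all genes or adjusted over the list alone, and library means of 5.21, 6.14 and 5.70 in HET and 6.31, 5.92 and 6.10 in WT. Its camera adjusted p was 1.69e-05, and its adjusted p was 0.453 with an estimated correlation. The score of that regional list was used as a covariate, chosen after the data were seen. With it, 5 genes were higher and 5 lower and the relative median of the fatty acid oxidation list was −0.28. Absorptive enterocyte and brush border genes had a relative median of 0.08, or −0.10 without WT 3. Their camera adjusted p was 0.562, or 0.00294 without WT 3. With an estimated correlation and all libraries it was 0.913.

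Scd2, a stearoyl-CoA desaturase, rose from 8.45 ± 3.41 to 40.2 ± 19.9 FPKM (SD, n = 3 each, log2 fold change 2.08 ± 0.36 SE, adjusted p = 0.0488), and it was the single called member of the fatty acid synthesis list, which did not pass (4 higher when adjusted over the list alone). Pcsk9, which lowers the LDL receptor at the cell surface, and Nsdhl, an enzyme of sterol synthesis, rose by log2 fold changes of 1.90 and 0.83. They were the 2 called members among 25 tested genes of cholesterol synthesis, of which 9 rose when adjusted over the list alone and 6 rose without WT 3. The relative median of this list was 0.31, with a camera adjusted p of 9.26e-05 and an adjusted p of 0.731 with an estimated correlation. Fbp1, an enzyme of gluconeogenesis, fell from 63.2 ± 22.8 to 15.5 ± 5.08 FPKM (−1.94 ± 0.34 SE, adjusted p = 0.0488), the only called member among 18 tested genes of gluconeogenesis and fructose handling, of which 2 fell when adjusted over the list alone. That list had a relative median of −0.50 (camera adjusted p = 0.000105, adjusted p = 0.731 with an estimated correlation), which was −0.83 without WT 3, where 2 members fell. The list of dietary lipid uptake had a relative median of −0.21 and no called member among 27, with 1 lower when adjusted over the list alone. Without WT 3 the relative median was −0.45, 2 members fell and the adjusted p was 3.18e-06. Its camera adjusted p was 0.00377, or 0.766 with an estimated correlation, and it went to 0.0515 without HET 1, 0.0958 without WT 2, 0.104 with median-of-ratios scaling, 0.393 with quantile normalization and 0.343 with the proximal score. Hsd17b13, a lipid droplet protein, Retsat, a retinol saturase, Rdh16f2, of the retinol dehydrogenase family, and the water and glycerol channel Aqp3 fell by 2.41, 1.62, 2.26 and 1.62 on the log2 scale.

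Of 42 cell cycle genes, 10 rose in HET intestine. Top2a, a topoisomerase of dividing cells, had a log2 fold change of 0.99 ± 0.13 SE (adjusted p = 0.0272), Kif11, a mitotic kinesin, had 0.96 ± 0.12 SE (adjusted p = 0.0238) and the mitotic kinase gene Aurkb had 0.89 ± 0.12 SE (adjusted p = 0.0322). Among 42 tested genes of S phase, G2 and M phase, 10 rose and none fell, and 39 rose when adjusted over the list alone. The relative median was 0.47, and 39 members had all 3 HET libraries above all 3 WT libraries. Camera gave adjusted p = 2.52e-20 and fry 0.0127, and with an estimated correlation the adjusted p was 0.424. Without WT 3 the relative median was 0.51 and 10 members rose. The DNA double strand break repair list, with no called member among 29 and 9 higher when adjusted over the list alone, had a relative median of 0.18 and a camera adjusted p of 0.000638, or 0.731 with an estimated correlation. With mean FPKM of at least 5 as the filter, its adjusted p was 0.641. The means of the smooth muscle, fibroblast and macrophage lists were also higher in each HET library than in each WT library. These means are not relative to all tested genes, and WT 3 had the lowest in each of these lists.

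Of 45 interferon-stimulated genes, Cxcl9, Zbp1 and Gbp2 rose in HET, and of 20 MHC class I genes Psmb9 rose. Cxcl9, a chemokine induced by interferon gamma, rose from 2.84 ± 0.0620 to 8.35 ± 0.498 FPKM (SD, n = 3 each, log2 fold change 1.28 ± 0.11 SE, adjusted p = 0.00764). Zbp1, a nucleic acid sensor, and the guanylate-binding protein gene Gbp2 rose by 1.53 and 1.02, and the immunoproteasome subunit gene Psmb9 rose by 0.94. Outside these lists, the ubiquitin-like gene Ubd rose by 2.25 (adjusted p = 0.0473, and 0.0572 without WT 3) and Oas1e, of the oligoadenylate synthetase family, by 2.16. Of 45 interferon-stimulated genes, 3 rose, none fell and 42 did not pass, and 9 rose when adjusted over the list alone. The relative median was 0.29 and the camera adjusted p was 0.00430, which went to 0.830 without WT 2 and 0.181 with the proximal score. With an estimated correlation the adjusted p was 0.809. In the MHC class I list, 1 of 20 rose and 7 rose when adjusted over the list alone (relative median 0.29, camera adjusted p = 0.00454, fry adjusted p = 0.0319, adjusted p = 0.731 with an estimated correlation). The MHC class II list had no called member among 11, 0 when adjusted over the list alone, and a relative median of 0.34. Its camera adjusted p was 0.0173, and its adjusted p was 0.731 with an estimated correlation. The macrophage and dendritic cell markers moved with these lists, at library means of 2.85 to 3.03 in HET and 2.27 to 2.62 in WT. The lowest was WT 3, and the means are not relative to all tested genes.

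Of the fibroblast and matrix markers, 2 rose in HET, and 8 further marker lists described here passed by camera with the preset correlation without a called member. None of these 9 lists passed with an estimated correlation or by fry. In the fibroblast and matrix list, Mfap4, a microfibril protein, and Col3a1, a fibrillar collagen, rose by log2 fold changes of 1.02 and 0.92, as 2 of 32 tested members, and 17 rose when adjusted over the list alone (relative median 0.35, camera adjusted p = 5.81e-05). The smooth muscle list had no called member among 25, 2 higher when adjusted over the list alone, and a relative median of 0.47 (camera adjusted p = 9.40e-05), with Des, the muscle intermediate filament desmin, at 52.5 ± 11.6 FPKM in HET and 29.1 ± 4.03 FPKM in WT. The macrophage and dendritic cell list, with Itgax at an adjusted p of 0.0544, had no called member among 26, and 11 rose when adjusted over the list alone (relative median 0.31, camera adjusted p = 0.000120). With an estimated correlation, the adjusted p was 0.731 for each of these 3 lists. Tuft cell markers had a relative median of 0.32 (camera adjusted p = 0.00806) and goblet cell markers of 0.37 (adjusted p = 0.0116), with no called member among 17 and 26 and 1 higher in each when adjusted over the list alone, and both had an adjusted p of 0.731 with an estimated correlation. The goblet list went to an adjusted p of 0.0795 without HET 1, 0.326 without WT 1 and 0.779 with the proximal score, with which the tuft list went to 0.108. B lymphocyte markers had no called member among 8, 3 higher when adjusted over the list alone, and a relative median of 0.30 (camera adjusted p = 0.0222, or 0.731 with an estimated correlation), and lost the call without HET 1, WT 2 or WT 3, at adjusted p of 0.0940, 0.157 and 0.103, with no filter (0.0506), with array weights (0.128) and with the proximal score (0.108). Tight junction and adherens junction genes had no called member among 29, 0 when adjusted over the list alone, and a relative median of 0.25, or 0.15 without WT 3 (camera adjusted p = 0.0216, or 0.803 with an estimated correlation), and went to 0.0566, 0.132 and 0.0556 without HET 2, HET 3 or WT 3 and to 0.0765 with TPM. Haemoglobin and erythroid genes were lower as a list, with a relative median of −0.98 over 6 members, none called and 5 lower when adjusted over the list alone (camera adjusted p = 2.56e-09, or 0.424 with an estimated correlation). Hba-a1, an alpha globin gene, was at 15.3 ± 3.25 FPKM in HET and 30.0 ± 4.54 FPKM in WT. The neutrophil list had a relative median of −0.41 over 8 members, none called over all genes or adjusted over the list alone (camera adjusted p = 0.00315, or 0.424 with an estimated correlation), and its adjusted p went to 0.0677 with median-of-ratios scaling and 0.0560 with quantile normalization.

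**Figure D3:**
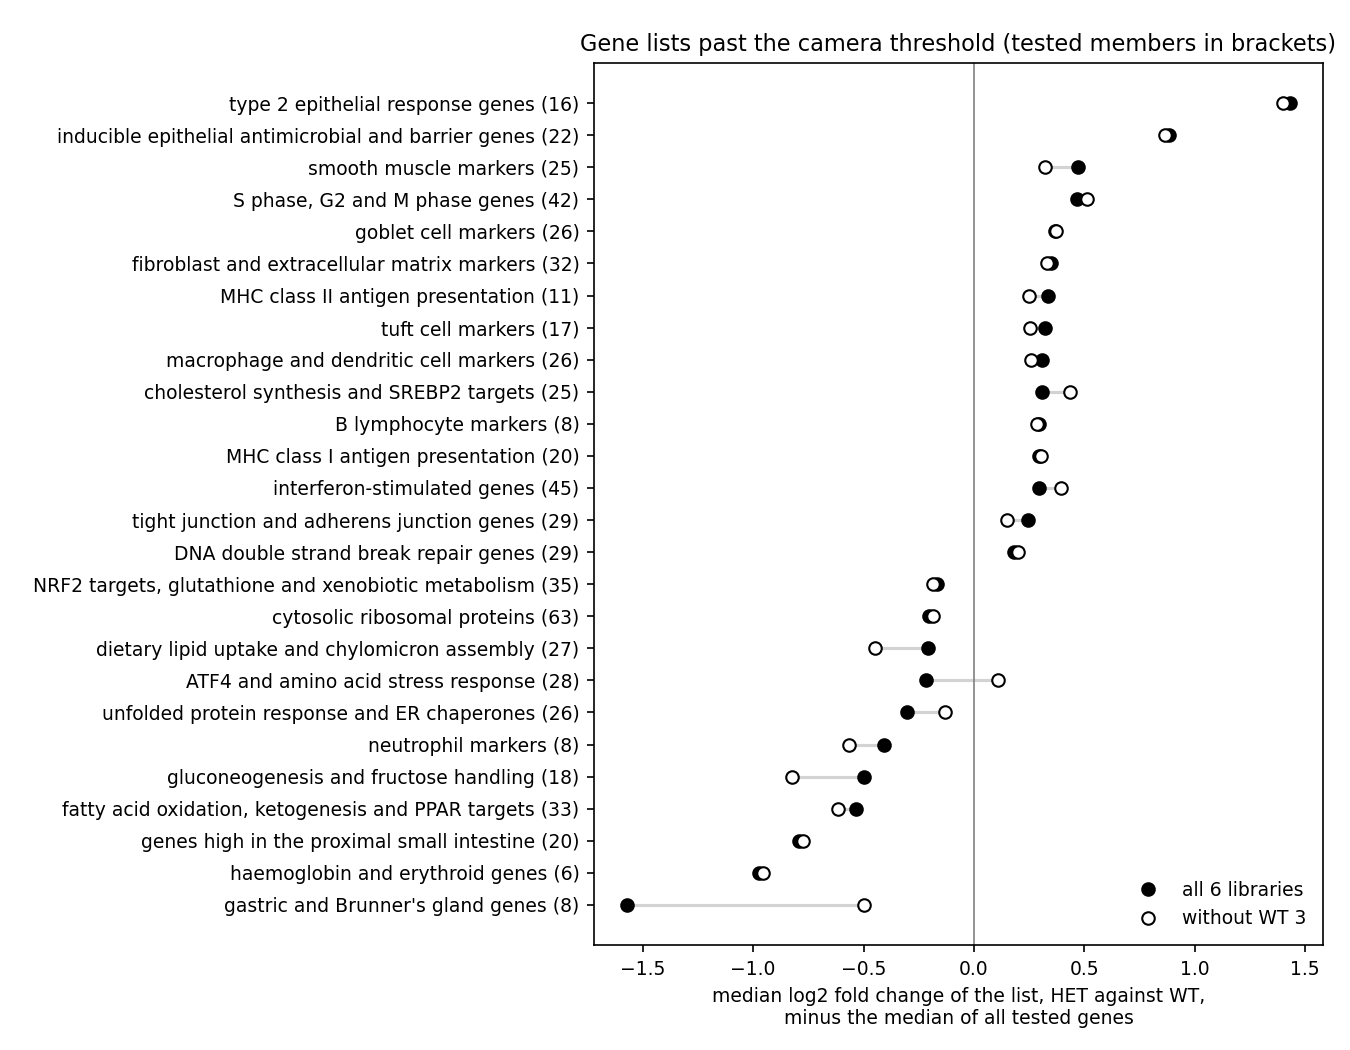
Median log2 fold change of each gene list past the camera threshold, HET against WT, minus the median of all tested genes, with the number of tested members in brackets. Filled points use all 6 libraries and open points leave out WT 3. The pancreatic list, at −3.78 with and 0.02 without WT 3, is left out for scale, and the ATF4 list crosses from −0.22 to 0.11.

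Of 35 NRF2 and xenobiotic genes, Gpx2 rose, Cyp1a1 fell and 33 did not pass, and the heat shock genes Hspa1b and Hspa1a fell. Cyp1a1 fell from 496.9 ± 219.8 to 71.8 ± 30.5 FPKM (SD, n = 3 each, log2 fold change −2.76 ± 0.43 SE, adjusted p = 0.0417, and 0.0503 without WT 3), and Tiparp, another target of the aryl hydrocarbon receptor, fell by 1.47 on the log2 scale. Gpx2, the gastrointestinal glutathione peroxidase, rose from 37.5 ± 10.7 to 205.3 ± 50.9 FPKM (2.42 ± 0.27 SE, adjusted p = 0.0185). Cyp1a1 and Gpx2 were the 2 called members among 35 of the NRF2 and xenobiotic list, with 1 higher and 2 lower when adjusted over the list alone, whose relative median was −0.17 (camera adjusted p = 0.00128, or 0.731 with an estimated correlation). That list went to an adjusted p of 0.228 without HET 1, 0.161 with quantile normalization and 0.779 with the proximal score. Cyp2c55, another cytochrome P450 gene, rose by 2.18. The heat shock genes Hspa1b and Hspa1a, whose near-identical copies can share reads, fell by 2.98 and 1.81 on the log2 scale, with adjusted p of 0.00148 and 0.00369. Cytosolic ribosomal protein genes had a relative median of −0.20 with no called member among 63, 0 when adjusted over the list alone (camera adjusted p = 4.11e-06, or 0.736 with an estimated correlation, and 0.0843 with array weights). AA467197 rose by 1.95.

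A further set of lists moved with WT 3. The pancreatic list had a relative median of −3.78 with WT 3 (camera adjusted p = 8.44e-12, or 0.731 with an estimated correlation) and 0.02 without it, where the adjusted p was 0.633. The gastric and Brunner's gland list went from a relative median of −1.57 and an adjusted p of 8.77e-05 to −0.50 and 0.293, the unfolded protein response list from −0.30 and 0.000105 to −0.13 and 0.322, and the ATF4 amino acid stress list from −0.22 and 0.00806 to 0.11 and 0.279. With an estimated correlation and all libraries, the adjusted p of each of these 3 lists was 0.731. With array weights it was 0.0645, 0.289 and 0.665. The gastric list also went to 0.0661 without the pancreatic transcripts, and the ATF4 list to 0.475 with a filter of 5 FPKM, 0.106 with median-of-ratios scaling, 0.0811 with quantile normalization, 0.0794 without the pancreatic transcripts and 0.382 with the ileum score. None of the 4 lists, of 28, 8, 26 and 28 tested members, had a called member, and adjusted over the list alone only the ATF4 list had 1, Ddit4, at a log2 fold change of 0.77.

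Lists on the fusion partners' own pathways did not pass. FOXO target genes that PI3K and AKT restrain had a relative median of 0.09 and a camera adjusted p of 0.662, with Irs2, an insulin receptor substrate induced by FOXO factors, as the 1 called member of 33 (log2 fold change 1.22 ± 0.19 SE, adjusted p = 0.0419) and 5 higher and 2 lower, G6pc and Gadd45b, when adjusted over the list alone. Components of PI3K, AKT and mTOR signalling had a relative median of 0.0086, or 0.06 without WT 3 (adjusted p = 0.628), with Pik3cg, a catalytic PI3K subunit, as the 1 called member of 32 (0.84 ± 0.14 SE, adjusted p = 0.0480, and 0.0594 without WT 3) and 1 higher when adjusted over the list alone. Neddylation genes had a relative median of −0.06, or −0.09 without WT 3, with no called member among 36 (adjusted p = 0.496), over all genes or adjusted over the list alone. With an estimated correlation these 3 lists had an adjusted p of 0.913, 0.906 and 0.906. The list of crypt stem cell markers had a relative median of 0.12 (adjusted p = 0.0579) with Clca3b, of the calcium-activated chloride channel regulator family, as the 1 called member of 26 (1.28 ± 0.19 SE, adjusted p = 0.0373), also the only one when adjusted over the list alone. Its adjusted p was 0.731 with an estimated correlation. Without WT 3 this list passed, at a relative median of 0.16 and a camera adjusted p of 0.0172. Wnt targets had a relative median of 0.06, or 0.10 without WT 3 (adjusted p = 0.159) and Paneth cell genes of 0.87 (adjusted p = 0.159), with no called member among 24 and 21, and 1 and 0 higher when adjusted over the list alone. With an estimated correlation their adjusted p was 0.792 and 0.906. Of 60 lists, 15 were higher and 12 lower by camera with the preset correlation. By camera with an estimated correlation 0 passed and 6 had an unadjusted p under 0.05, and 4 passed by fry. Those 4 were higher in HET, the direction in which WT 3 moves other genes, and fry does not correct for that shift.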

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

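Rows of the table that carry no gene symbol and enter no comparison of the report still differed between the groups. Of 5 such rows with a mean of at least 0.5 FPKM, 4 had all 3 HET libraries above all 3 WT libraries and 0 had all 3 below. The row with the largest difference was at 2.71 ± 0.225 FPKM in HET and 0.542 ± 0.193 FPKM in WT (SD, n = 3 each). These rows cannot be tied to a gene, and no explanation was tested.

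For the number of changed genes and their excess of higher ones, no test was chosen only after its own result was seen, but the rescaling without pancreatic transcripts was added after the data were examined. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, called as many as 119 genes and the highest other called 3, but 10 splits are too few for a share under 0.05. Passenger DNA around Pten stays open, as 8 of 117 called genes lay on chromosome 19, 6.84% against 3.67% of tested genes (one-sided Fisher exact p = 0.0664). Of the 50 nearest tested genes 1 was called, against 119 of all 12519. The test presumes that the fusion allele lies at Pten, but the labels do not say how it was made. Genes near Nedd8 were not examined. The excess of higher genes fits pancreatic transcripts taking reads of WT 3, since 36.1% of called genes were higher after these were left out.

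For the lower fatty acid oxidation and PPAR target list, the tests with the ileum score, with the proximal score and on feeding were chosen only after the data were seen, the ileum test before its own value was seen, while leaving out WT 3 was planned and its bound was set afterwards. Pancreatic transcripts do not account for it, as the relative median was −0.53 with WT 3 and −0.62 without it. With the ileum score the relative median stayed at −0.52 (spread 0.14, the standard error of the median over list members), more than 50% of −0.53. This cannot exclude position along the intestine, since the score differed between the groups mainly through WT 3. It was 0.62, −0.28 and 0.16 in HET and 0.23, 0.19 and −0.92 in WT. The trend that the proximal score follows stays open, as its scores overlap between the groups (HET −0.80, 0.26 and −0.20, WT 0.64, 0.18 and −0.08). That score as a covariate left −0.28 (spread 0.11), within the spread of 50% of −0.53. The spread treats list members as independent and does not measure variation between libraries. Time since feeding could not be told apart either, with the cholesterol synthesis list at a relative median of 0.31.

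For the higher epithelial defence genes, the tests with the ileum and proximal scores were chosen only after the result was seen, while leaving out WT 3 was planned and its bound was set afterwards. The 6 called members kept at least 78.2% of their log2 fold change with the ileum or proximal score. Both scores use FPKM as deposited, lowered in WT 3 by its pancreatic share. They therefore cannot decide whether position along the intestine accounts for these genes. With the proximal score, which takes up 1 degree of freedom, 3 of 6 passed and 3 did not: of the latter, Gsdmc4 went from 6.11 ± 0.86 SE to 4.93 ± 0.73 (adjusted p = 0.125), Sprr2a1 from 2.18 ± 0.32 to 1.80 ± 0.31 (0.177) and Nox1 from 0.93 ± 0.15 to 0.996 ± 0.19 (0.209). Pancreatic transcripts do not account for these genes, as 6 of 6 were still called without WT 3. These 6 are the called higher members only, and 1 member of the antimicrobial list was called lower without WT 3.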

How the results depend on the processing

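The count of changed genes was the least stable result. Under each alternative with all 6 libraries and under each left-out library, every tested gene of the 119 kept its sign. In each of these genes all HET values lie on one side of all WT values. Their sign was therefore fixed in advance for left-out libraries, filters, pseudocounts, eBayes options and the replicate block, and could change only with rescaling or a covariate. Changed genes (higher and lower) numbered 13 (5 and 8) with no filter, 31 (14 and 17) with median-of-ratios scaling, 47 (25 and 22) with quantile normalization, 267 (230 and 37) with robust eBayes, 838 (607 and 231) with array weights and 429 (375 and 54) at an adjusted p under 0.10. An unadjusted p under 0.05 with at least 2-fold change gave 68 lower genes. Of alternatives chosen after seeing the data, leaving out the pancreatic transcripts gave 36 (13 and 23), the proximal score covariate gave 10 (5 and 5), the ileum score covariate gave 118 (83 and 35), and voom on the recovered reads gave 167 with 114 of the 119 among them. Leaving out 1 library gave 6 to 211 changed genes, 2 to 119 higher and 4 to 92 lower, and loses a degree of freedom. Equal replicate numbers did not pair the libraries, with correlations of deviations of −0.06, −0.37 and −0.26, and no HET library correlated best with its own number. With the replicate number as a block, 1 gene was called, 0 higher and 1 lower (Hspa1b, adjusted p = 0.0338; 1880 genes had an unadjusted p under 0.05 in limma), the tight junction list went to an adjusted p of 0.0514, and this fit has 2 degrees of freedom fewer. Gene lists higher and lower numbered 0 and 0 by camera with an estimated correlation and 4 and 0 by fry. Pten, Nedd8 and Ddx3y turned to log2 fold changes of −0.15, −0.12 and −0.14 with median-of-ratios scaling, −0.12, −0.043 and −0.10 with quantile normalization (Kdm5d −0.012), −0.13, −0.10 and −0.12 without pancreatic transcripts, and −0.033, −0.017 and −0.083 with the ileum score. With array weights Pten and Ddx3y turned to −0.099 and −0.070, and the ATF4 list turned higher at an adjusted p of 0.665. Leaving out 1 library gave log2 fold changes of −0.083 to 0.10 for Pten, −0.054 to 0.18 for Nedd8, −0.13 to 0.14 for Ddx3y, −0.12 to 0.63 for mt-Nd3 and −0.0039 to 0.43 for Stmn3, and adjusted p of 2.35e-23 to 0.633 for the pancreatic list and 3.62e-06 to 0.279 for the ATF4 list. The tools edgeR and DESeq2, planned for a file of counts, were not run on the recovered reads. The cause of the other shifts was not tested.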

Other observations

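Genes that, except for the clock list member Per1, lay outside the fixed lists were chosen after their values were seen. Zbtb16 and Klf9, transcription factor genes induced by glucocorticoids, rose in HET by log2 fold changes of 1.74 ± 0.11 SE (3.14 ± 0.308 against 0.235 ± 0.0200 FPKM, SD, n = 3 each, limma adjusted p = 0.00148) and 0.89 ± 0.15 SE (adjusted p = 0.0473). The clock gene Per1, also induced by glucocorticoids, was at 11.4 ± 2.59 FPKM in HET and 4.52 ± 1.30 FPKM in WT (adjusted p = 0.0598). Hsph1, a heat shock chaperone gene, fell with Hspa1a and Hspa1b, from 47.7 ± 5.38 to 19.6 ± 2.29 FPKM (−1.24 ± 0.16 SE, adjusted p = 0.0272). The chaperone genes Dnaja1 and Hsp90aa1 were at adjusted p of 0.0832 and 0.107. Beside Cyp1a1 and Tiparp, the aryl hydrocarbon receptor targets Cyp1b1 (3.42 ± 0.168 against 11.4 ± 5.12 FPKM, adjusted p = 0.0849) and Ahrr (0.715 ± 0.0276 against 2.67 ± 0.948 FPKM, adjusted p = 0.0532) did not pass. No hypothesis was tested on these genes.

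The iron transport genes Slc40a1 and Cybrd1 were at 76.5 and 72.4 FPKM in WT 3, 11.6 and 7.37 FPKM in HET 2, and lower in the other 4 libraries.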
